A study of Mus musculus with 11 samples.

How the data were processed

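Total RNA from whole mouse pancreas was biotin-labelled and hybridised to Affymetrix arrays, with 1 array per sample. The labels give 11 samples, of which 5 came from mice injected with sodium chloride (NaCl) and 6 from mice injected with caerulein. The series text counts 4 control mice, whereas the sample titles name 5 control samples, and all 5 were used. The titles give each sample its group and replicate number. Nothing in the labels says outright that each sample is a separate mouse, so the p-values measure the spread between these samples. Degraded RNA had been excluded before hybridisation, per the labels' protocols.

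The authors deposited log2 expression values, 1 per probe set and array. Per the submitters' processing notes, RMA (robust multi-array average) and the R packages oligo and limma were used; their versions are not given in the sources used here. RMA as usually run corrects the background, quantile-normalises the probes between arrays and summarises the probes of a probe set to 1 value. The deposited log2 values had no missing entries, and no pair of arrays held identical values. The median log2 value per array lay between 5.35 and 5.40 in the NaCl group and between 5.20 and 5.25 in the caerulein group, so the summarised values were not equal in distribution between arrays. No detection calls, background intensities, scan dates or batches were analysed here. Whether a dim probe set lies above background is therefore unknown, and no gene was read as more expressed than another from their levels. Mean levels served only to pick a probe set per gene, to leave out or bin probe sets, and to match random lists. RMA values can compress changes at both ends of the range, and the number of arrays limits the precision.

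Of the 35556 probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 carried several, and 12146 were not listed there and stayed unnamed. Symbols were checked through their Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, used only for names. This matched 21698 of the single-symbol probe sets and renamed 0. No genome build is given in the sources used here, so no coordinates are reported. No gene was named from a probe set with several symbols. The 19938 genes with a single-symbol probe set were each represented by the probe set with the highest mean over all 11 arrays, and 999 genes had more than 1 probe set. Some members of the gene lists are not reported here.

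Caerulein was compared with NaCl in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with default settings, no covariates, two-sided). Benjamini-Hochberg adjustment ran over all 35556 probe sets, and the threshold was an adjusted p under 0.05, with and without an absolute log2 difference of at least 1. All adjusted p-values of genes come from this fit unless another test is named. A difference is the caerulein mean minus the NaCl mean on the log2 scale, given with the standard error (SE) of the fit.

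Before the data were examined, 33 gene lists and a scaling list were fixed from general knowledge of the pancreas and of inflammation. Together they held 632 different symbols. In the 33 lists 566 memberships were measured. The 32 lists with at least 5 measured members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists). Members past the threshold were counted over all probe sets and adjusted over the list alone. The genes named in the text were also set by a rule fixed at that time. The rule took the 8 largest rises and the 8 largest falls among genes past the threshold whose caerulein arrays all lay beyond all NaCl arrays, leaving out predicted and RNA genes. From each list it took the 2 members past the threshold with the largest change, and the 1 member past the threshold with the largest change against the list's majority. For a list with no member past the threshold it took the member with the smallest p. Genes outside this rule are said to have been chosen after their values were seen.

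The fit was tested on simulated data for the 11 arrays and 35556 probe sets, with 50 genes changed at each size. It recovered 0 of 50 genes changed by 0.25 on the log2 scale, 28 (56%) at 0.5, 43 (86%) at 1 and 50 (100%) at 2, and 7 of its 128 calls were false. In a separate simulation of the 32 lists, camera called the 1 list that had been moved and 1 list that had not. Noise in both simulations was drawn independently for each probe set. In the first, far fewer probe sets were changed than passed in the data (44.2%). The recovered shares and false calls therefore do not describe the data, where for example Gp2 passed at -0.19 (limma adjusted p = 0.00777).

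The alternatives were a trended robust variance prior, array quality weights, a shift of each array to an equal mean of a scaling list of commonly used reference genes or to an equal 75th percentile, a second quantile normalisation, leaving out the dimmer 50 percent of the probe sets, the replicate number as a block, each array left out in turn, a threshold of 0.01, an exact rank-sum test, limma's treat against a 2-fold change, the mean of all probe sets of a gene, camera with an estimated correlation, and fry. Cyclic loess normalisation and the comparison of list medians with 10000 random lists matched on mean level were added after the data had been seen. For the closing tests, medians were bootstrapped 10000 times, 100 splits of the arrays were drawn, and Dixon's rule at 95 percent was applied to each group. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.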

Results

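Gene expression was measured in the pancreas of wild-type C57BL/6J mice after experimental acute pancreatitis. Caerulein, a peptide that acts on cholecystokinin receptors and overstimulates the enzyme-secreting acinar cells, was given as 9 hourly intraperitoneal injections. The series record states the dose as 50 mg/kg, a unit that was not checked here. Control mice received sodium chloride (NaCl). The time between the last injection and tissue collection is not given in the sources used here. There were 6 caerulein and 5 NaCl arrays, each with log2 values for 35556 probe sets. The comparison asks which transcripts differ in the pancreas between caerulein and NaCl.

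In caerulein pancreas, the keratin genes Krt8 and Krt19, the claudin gene Cldn4 and most of a list of cytoskeleton and cell-junction genes were strongly higher. Most members of the heat shock, integrated stress response, oxidative stress, immediate-early and ribosome biogenesis lists were also higher. The list calls of the first 3 were lost with an estimated correlation (camera adjusted p = 0.0758, 0.106 and 0.173). Lower were most of a list of acinar transcription factors and receptors, among them the receptor for cholecystokinin, many endoplasmic reticulum chaperones and most of a list of amino acid metabolism genes. The calls of these 3 lower lists were also lost with an estimated correlation (camera adjusted p = 0.239, 0.395 and 0.235). With an equal scaling list mean they were lost too (camera adjusted p = 0.0704, 0.0619 and 0.161), although more members were lower there. As deposited, 11 of 18 macrophage markers were higher. Of the neutrophil markers 13 of 18 did not pass, and of the digestive enzyme list 14 of 24 members. These 3 counts depended on the scaling, as given with each list. The log2 difference passed the threshold for 15713 of 35556 probe sets (44.2%; limma, adjusted p under 0.05), of which 5829 were higher and 9884 lower. With a change of at least 2-fold, 1736 were higher and 373 lower as deposited, against 627 and 3802 with an equal mean of the scaling list. Among 19938 named genes, 4051 were higher and 6839 lower. In 3325 genes every caerulein array lay above every NaCl array and in 4101 every one lay below, against 0.433% of genes expected in the 2 directions by chance.

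The median difference over all genes was -0.13 and over all probe sets -0.11, and differences below are to be read relative to it. With an equal scaling list mean the median over all probe sets was -0.67. The arrays separated by group, with 62.8% of the variance on the first principal component and 6.56% on the second. Correlations were 0.981 to 0.991 within groups and 0.938 to 0.955 between them. The balance of the calls depended on the scaling. As deposited, 62.9% of the called probe sets were lower, against 46.4% after cyclic loess normalisation (added after the data had been seen), 72.1% with equal 75th percentiles and 92.5% with an equal mean of the scaling list. The share fell to 54.1% when the dimmer 50 percent of the probe sets was left out. Of the 2109 probe sets called with at least 2-fold change, 2085 to 2109 stayed called in the same direction under the 4 rescalings.

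The largest rise was that of Cldn4, which encodes a tight-junction claudin. Its log2 expression was 6.43 ± 0.36 (SD, n = 5) in NaCl and 12.19 ± 0.29 (SD, n = 6) in caerulein, a 54.3-fold difference (limma adjusted p = 1.0e-10). Rcan1, a regulator of calcineurin, was 42.4-fold higher (log2 difference 5.40, SE 0.13, limma adjusted p = 1.9e-11). Itpkc, an inositol trisphosphate kinase, was 21.4-fold higher and the duct keratin Krt19 20.9-fold higher. The aldo-keto reductase Akr1b8, the MAP kinase phosphatase Dusp1, the epithelial keratin Krt8 and Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, were 19.5-fold to 20.7-fold higher. The largest fall was that of Cckar, the cholecystokinin receptor of acinar cells, from 11.10 ± 0.14 (SD, n = 5) to 7.05 ± 0.24 (SD, n = 6), or 16.6-fold (limma adjusted p = 5.2e-11). Gatm, which catalyses the first step of creatine synthesis, was 9.36-fold lower, and the clock output gene Dbp 9.03-fold lower. The amino acid transporter gene Slc7a8 was 7.47-fold lower. Lrrn1, the nucleotide-sugar receptor gene P2ry14, the lysine-degrading enzyme gene Aass and Sostdc1 were 6.17-fold to 6.95-fold lower. By the rule that chose them, the arrays of the 2 groups did not overlap for any of these 16 genes.

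**Figure D1:**
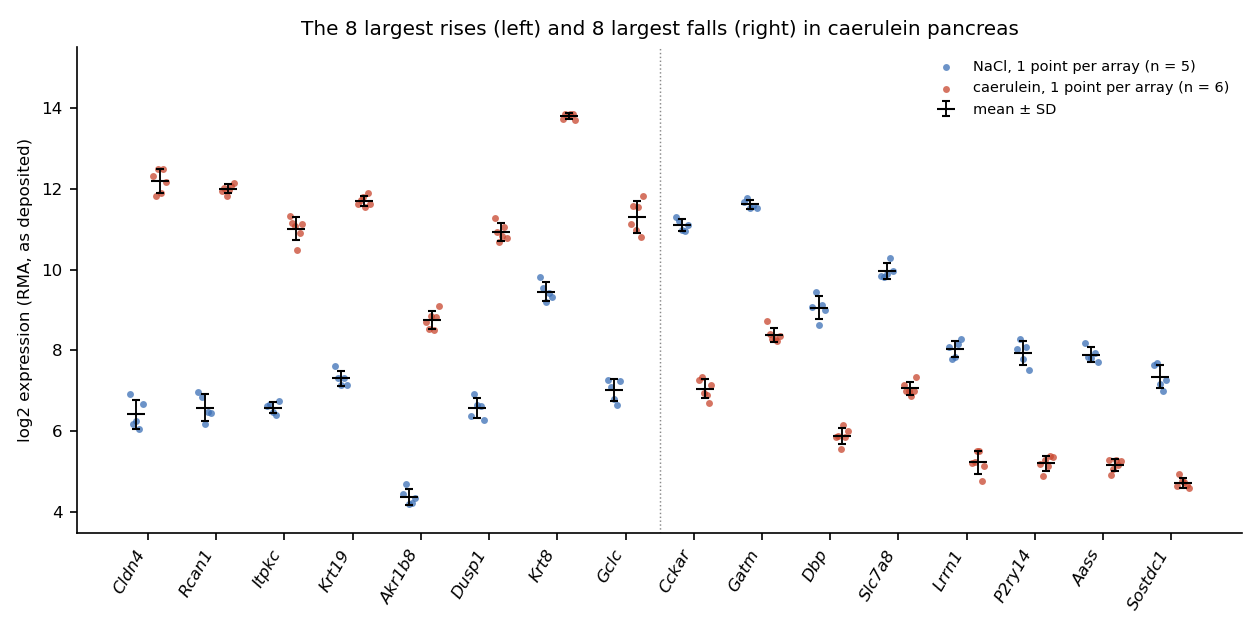
Log2 expression of the 8 genes with the largest rise and the 8 with the largest fall, 1 point per array, for 5 NaCl and 6 caerulein arrays, with bars for the mean ± SD. The groups do not overlap for any gene, and the differences run from 5.76 for Cldn4 to -4.05 for Cckar.

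Of 13 measured acinar transcription factors and receptors, 9 were lower and 2 higher, with a median difference of -0.80 (camera adjusted p = 0.0129). The call was lost with an estimated correlation (adjusted p = 0.239) and with an equal scaling list mean (adjusted p = 0.0704), although 12 were lower and 0 higher there, with a median of -1.37. The list also held the secreted hormone gene Fgf21, whose own difference of -0.80 was the list median as deposited. The factors were not counted apart from the other members. Bhlha15, a transcription factor of the secretory programme, was 4.00-fold lower. Ptf1a, the factor that specifies the acinar lineage, was higher by 0.55 (SE 0.15, limma adjusted p = 0.00823), but not after a second quantile normalisation (0.28, adjusted p = 0.164) or with an equal scaling list mean (-0.0098). Of 24 genes in the digestive enzyme list, 10 were lower, 0 higher and 14 not past the threshold. The median was -0.11 as deposited and -0.68 with an equal scaling list mean (camera adjusted p = 0.0245, direction lower, and adjusted p = 0.326 with an estimated correlation). As deposited it lay 0.019 above the median of all genes, opposite to the direction of the test. The list also held the colipase gene Clps and the granule protein genes Sycn, Gp2 and Zg16, which encode no enzymes and were all lower. The number lower was 19 with equal 75th percentiles and 23 with an equal scaling list mean. The enzyme median as deposited lay inside the range of random lists matched on mean level (-0.17 to 0.67). The chymotrypsin Ctrc was 2.62-fold lower and the ribonuclease Rnase1 1.64-fold lower. Of the 24 list members, 19 had a mean level of 13 or more, near the highest value on any array (15.0). Trypsin, amylase and Reg genes have near-identical copies that their probes may not separate.

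Endoplasmic reticulum chaperones and unfolded protein response genes were mostly lower, with 16 of 25 lower, 3 higher and a median of -0.50 (camera adjusted p = 0.00229). This call was lost with an estimated correlation (adjusted p = 0.395) and with an equal scaling list mean (adjusted p = 0.0619), although 22 were lower there, with a median of -1.07. Sel1l, part of the pathway that degrades misfolded proteins, fell 5.97-fold, and Ero1b, an oxidase for disulphide bonds in secretory cells, 4.29-fold. Its relative Ero1a was 2.75-fold higher. In the list of pancreatic amino acid and polyamine metabolism, 12 of 17 genes were lower and 2 higher, with a median of -0.46 (camera adjusted p = 0.00426). This call too was lost with an estimated correlation (adjusted p = 0.235) and with an equal scaling list mean (adjusted p = 0.161), although 14 were lower there, with a median of -1.03. Gatm was the largest fall there, while Sat1, the enzyme that acetylates polyamines, was 8.12-fold higher. Of 23 oxidative phosphorylation genes, 17 were lower and 2 higher, with a median of -0.34 (camera adjusted p = 0.0106). The adjusted p was 0.381 with an estimated correlation and 0.0577 with an equal scaling list mean, where 21 were lower with a median of -0.90. Sdhb, a subunit of succinate dehydrogenase, fell 1.97-fold, and Cycs, which encodes cytochrome c, rose 2.08-fold.

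The list of duct and acinar-to-ductal metaplasia markers was higher, with 12 of 20 genes higher, 5 lower and a median of 1.19 (camera adjusted p = 8.7e-06). Adjusted over the list alone, 13 were higher and 5 lower, and with an estimated correlation the adjusted p was 0.0624. Over all probe sets, 10 were higher and 8 lower with an equal scaling list mean, where the median was 0.63. Cldn4 and Krt19 led the rise, whereas the mucin gene Muc1 fell 2.21-fold. Cytoskeleton and cell-junction genes were mostly higher, with 23 of 24 higher, 1 lower and a median of 2.03 (camera adjusted p = 4.9e-20, and adjusted p = 0.00620 with an estimated correlation). The calcium-binding S100a11 was 16.9-fold higher and the membrane-binding annexin gene Anxa2 15.1-fold higher.

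Immediate-early genes rose in 17 of 22 cases, with 2 lower and a median of 1.24 (camera adjusted p = 2.0e-10, and adjusted p = 0.0247 with an estimated correlation). Adjusted over the list alone, 18 were higher. Dusp1 and the stress-induced factor Atf3 were 20.3-fold and 18.3-fold higher, and Egr3 was 1.42-fold lower. All 13 measured heat shock genes were higher, with a median of 1.72 (camera adjusted p = 1.0e-10, and adjusted p = 0.0758 with an estimated correlation). The chaperone genes Hsp90aa1 and Hspb1 were 8.96-fold and 8.66-fold higher. Of 18 targets of ATF4, the factor of the integrated stress response, 15 were higher and 1 lower, with a median of 1.26 (camera adjusted p = 3.3e-10, and adjusted p = 0.106 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, was 6.23-fold higher and Sesn2 5.48-fold higher. The oxidative stress and metallothionein list had 12 of 19 genes higher and 2 lower, with a median of 1.10 (camera adjusted p = 1.5e-06, and adjusted p = 0.173 with an estimated correlation). The counts were 11 higher and 8 lower, with a median of 0.53, with an equal scaling list mean. Its leading genes were Gclc and the sulfiredoxin Srxn1, 12.6-fold higher. Of 21 ribosome biogenesis genes, 19 were higher and 0 lower, with a median of 1.08 (camera adjusted p = 1.9e-13, and adjusted p = 0.0370 with an estimated correlation). Adjusted over the list alone, 20 were higher. The nucleolar protein genes Nop58 and Mybbp1a were 4.84-fold and 3.08-fold higher.

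Monocyte and macrophage markers were higher for 11 of 18 genes and lower for 0, with a median of 0.64 (camera adjusted p = 3.6e-05, and adjusted p = 0.275 with an estimated correlation). Adjusted over the list alone, 12 were higher. With an equal scaling list mean, 6 were higher and 6 lower, with a median of 0.07. The endotoxin co-receptor gene Cd14 was 4.94-fold higher and the lysozyme gene Lyz2 4.02-fold higher. Neutrophil markers gave no list call (camera adjusted p = 0.576, direction higher), and their median of -0.02 had the opposite sign to the test; it was 0.12 after a second quantile normalisation, 0.16 after cyclic loess, -0.08 with equal 75th percentiles and -0.58 with an equal scaling list mean. The neutrophil median as deposited lay above the range of 10000 random lists matched on mean level (-0.28 to -0.097). By this comparison, added after the data had been seen, the list was higher than genes of similar level. Of 18 neutrophil markers, 2 were higher and 3 lower, or 2 and 2 adjusted over the list alone, with Clec4d at 2.79-fold higher. With equal 75th percentiles 2 were higher and 5 lower, and with an equal scaling list mean 1 was higher and 14 lower, whereas 3 were higher and 0 lower after a second quantile normalisation and after cyclic loess. Of 25 cytokine and chemokine genes, 10 were higher and 3 lower, with a median of 0.15 as deposited and -0.42 with an equal scaling list mean (camera adjusted p = 0.0363, and adjusted p = 0.320 with an estimated correlation). Without NaCl replicate 1 the adjusted p of this list was 0.0537. Lif, an interleukin-6-type cytokine, was 5.46-fold higher and the chemokine Cxcl16 2.39-fold higher, while Csf3, a granulocyte growth factor, was 1.40-fold lower. Of 16 NF-kB targets and regulators, 9 were higher and 1 lower, or 9 and 2 adjusted over the list alone, with a median of 0.32 that became -0.25 with an equal scaling list mean. The list's camera adjusted p was 0.0112 as deposited, 0.132 with an estimated correlation, 0.0629 with an equal scaling list mean and 0.0647 without the dimmer 50 percent of the probe sets. The NF-kB subunit gene Rel and the inhibitor gene Nfkbia were 2.14-fold and 2.13-fold higher, and the mitochondrial superoxide dismutase gene Sod2 was 1.60-fold lower.

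The acute phase and complement list had 9 of 18 genes higher and 2 lower, or 9 and 4 adjusted over the list alone, with a median of 0.46 as deposited and -0.10 with an equal scaling list mean. Its camera adjusted p was 0.00211, and its adjusted p was 0.0758 with an estimated correlation. The iron-siderophore binding protein gene Lcn2 was 19.3-fold higher and the serine protease inhibitor gene Serpina3n 10.6-fold higher. Fgg, the fibrinogen gamma chain, had a difference of -0.25 as deposited, but the call ended after a second quantile normalisation (adjusted p = 0.111) and after cyclic loess (adjusted p = 0.161). Of 16 interferon-stimulated genes, 7 were higher and 0 lower, with a median of 0.34 as deposited and -0.23 with an equal scaling list mean (camera adjusted p = 0.00103, and adjusted p = 0.275 with an estimated correlation). After a second quantile normalisation 10 were higher, and after cyclic loess 12. The antiviral genes Rsad2 and Ifit3 were 2.12-fold and 2.06-fold higher.

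T and NK cell markers had 11 of 17 genes lower and 0 higher, and B and plasma cell markers 6 of 16 lower and 0 higher, with medians of -0.23 and -0.24 against -0.13 for all genes. Neither list passed camera (adjusted p = 0.0992 and 0.0944), although the B cell list did without caerulein replicate 2 (adjusted p = 0.0467). The numbers lower were 12 and 12 with equal 75th percentiles, 17 and 16 with an equal scaling list mean, 2 and 1 after a second quantile normalisation, and 1 and 0 after cyclic loess. Cd8a was 1.31-fold lower. Cd79b, a chain of the B cell receptor, had a difference of -0.34 as deposited, with an adjusted p of 0.162 after a second quantile normalisation and 0.317 after cyclic loess. Mast cell markers had 4 of 10 genes lower and a median of -0.18 (camera adjusted p = 0.238); 1 was lower after a second quantile normalisation, 0 after cyclic loess and 10 with an equal scaling list mean. The tryptase gene Tpsb2 had a difference of -0.36 (adjusted p = 0.0798 after cyclic loess), and Gata2 one of -0.29 (adjusted p = 0.0871 after a second quantile normalisation and 0.192 after cyclic loess).

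Extracellular matrix and wound-response genes were higher for 15 of 21 members and lower for 2, with a median of 0.64 (camera adjusted p = 1.4e-06, and adjusted p = 0.0501 with an estimated correlation). With an equal scaling list mean, 9 were higher and 6 lower, with a median of 0.08. The matrix glycoprotein gene Thbs1 was 8.43-fold higher and Hbegf, a ligand of the epidermal growth factor receptor, 5.81-fold higher. The metalloproteinase gene Mmp10 had a difference of -0.29 as deposited, with an adjusted p of 0.184 after a second quantile normalisation and 0.343 after cyclic loess. Stellate cell and fibroblast markers had 6 of 18 genes higher and 2 lower, with a median of 0.14 as deposited and -0.42 with an equal scaling list mean. Their camera adjusted p was 0.0561, and it lay between 0.0218 and 0.0467 without NaCl replicate 3 or caerulein replicates 1, 2 or 3. Pdpn and the intermediate filament gene Vim were 2.41-fold and 2.04-fold higher, and the proteoglycan gene Lum was 1.71-fold lower. Endothelial markers had 4 of 14 genes higher and 2 lower, with a median of 0.11 as deposited and -0.45 with an equal scaling list mean (camera adjusted p = 0.180). Pecam1 was 1.31-fold higher as deposited and -0.17 on the log2 scale with an equal scaling list mean, and Sox17 was 1.49-fold lower.

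Lysosome and autophagy genes were higher for 9 of 18 members and lower for 2, with a median of 0.22 as deposited and -0.34 with an equal scaling list mean (camera adjusted p = 0.00344). This call was lost with an estimated correlation (adjusted p = 0.241), a second quantile normalisation (adjusted p = 0.236), cyclic loess (adjusted p = 0.110) and without the dimmer 50 percent of the probe sets (adjusted p = 0.0647). The lysosome list median as deposited lay inside the range of random lists matched on mean level (-0.24 to 0.62). The lysosomal protease genes Ctsl and Ctsz were 4.41-fold and 3.35-fold higher, and the autophagy kinase gene Ulk1 was 1.30-fold lower. Regulated cell death genes were higher for 10 of 17 members and lower for 1, or 10 and 2 adjusted over the list alone, with a median of 0.25 as deposited and -0.31 with an equal scaling list mean. The camera adjusted p was 0.00251, and the adjusted p was 0.146 with an estimated correlation. The receptor genes Tnfrsf12a and Tnfrsf1a were 6.34-fold and 3.15-fold higher, and the pro-apoptotic gene Bbc3 was 1.25-fold lower. Regenerating and acinar injury proteins had 4 of 14 genes higher and 4 lower, or 4 and 5 adjusted over the list alone. Their median was 0.19 as deposited and -0.37 with an equal scaling list mean, where 4 were higher and 7 lower, and the camera adjusted p was 0.256 and 0.00995 in these 2 settings. The test's direction was higher in both, opposite to the sign of the second median. Reg3b was 5.65-fold higher with a wide spread in caerulein (9.09 ± 1.49, SD, n = 6), and the stress protein gene Nupr1 4.61-fold higher. For Reg3b, caerulein replicates 1 to 3 lay between 7.84 and 7.96 and replicates 4 to 6 between 9.13 and 11.3. Of 21 cell cycle and DNA replication genes, 3 were higher and 9 lower, or 3 and 10 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.655). The numbers higher and lower were 4 and 5 after a second quantile normalisation, 4 and 4 after cyclic loess, and 1 and 18 with an equal scaling list mean. The replication genes Mcm6 and Pcna were 3.15-fold and 1.64-fold higher, although Pcna did not pass with an equal scaling list mean (adjusted p = 0.0852).

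Islet markers were lower for 8 of 17 genes and higher for 0, or 9 and 0 adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.192). The number lower was 6 after a second quantile normalisation, 2 after cyclic loess and 15 with an equal scaling list mean. The beta-cell factor gene Mafa was 1.57-fold lower and the glucose transporter gene Slc2a2 1.46-fold lower. Adipocyte markers were lower for 7 of 11 genes, with a median of -0.36 (camera adjusted p = 0.0944, and 0.0355 without caerulein replicate 6). After a second quantile normalisation and after cyclic loess 3 were lower, with medians of -0.23 and -0.18, and with an equal scaling list mean 10. Lpl, which encodes lipoprotein lipase, and the lipid-droplet gene Plin4 had log2 differences of -0.65 and -0.58. Intestinal epithelium markers were lower for 5 of 10 genes, or 6 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0944). In these 3 settings 3, 3 and 10 of them were lower, with medians of -0.10, -0.08 and -0.79. Lct, which encodes lactase, and the intestinal factor gene Cdx1 were 1.37-fold and 1.36-fold lower. None of 8 mesothelial markers passed the threshold (limma), with a median of -0.14 and a camera adjusted p of 0.776; 7 were lower with an equal scaling list mean, and 2 were higher after cyclic loess. Of 4 measured erythroid markers, too few for a list test, 3 were lower as deposited, 1 after a second quantile normalisation, 0 after cyclic loess and 4 with an equal scaling list mean, and Alas2 had a difference of -0.36 (adjusted p = 0.0842 after cyclic loess).

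**Figure D2:**
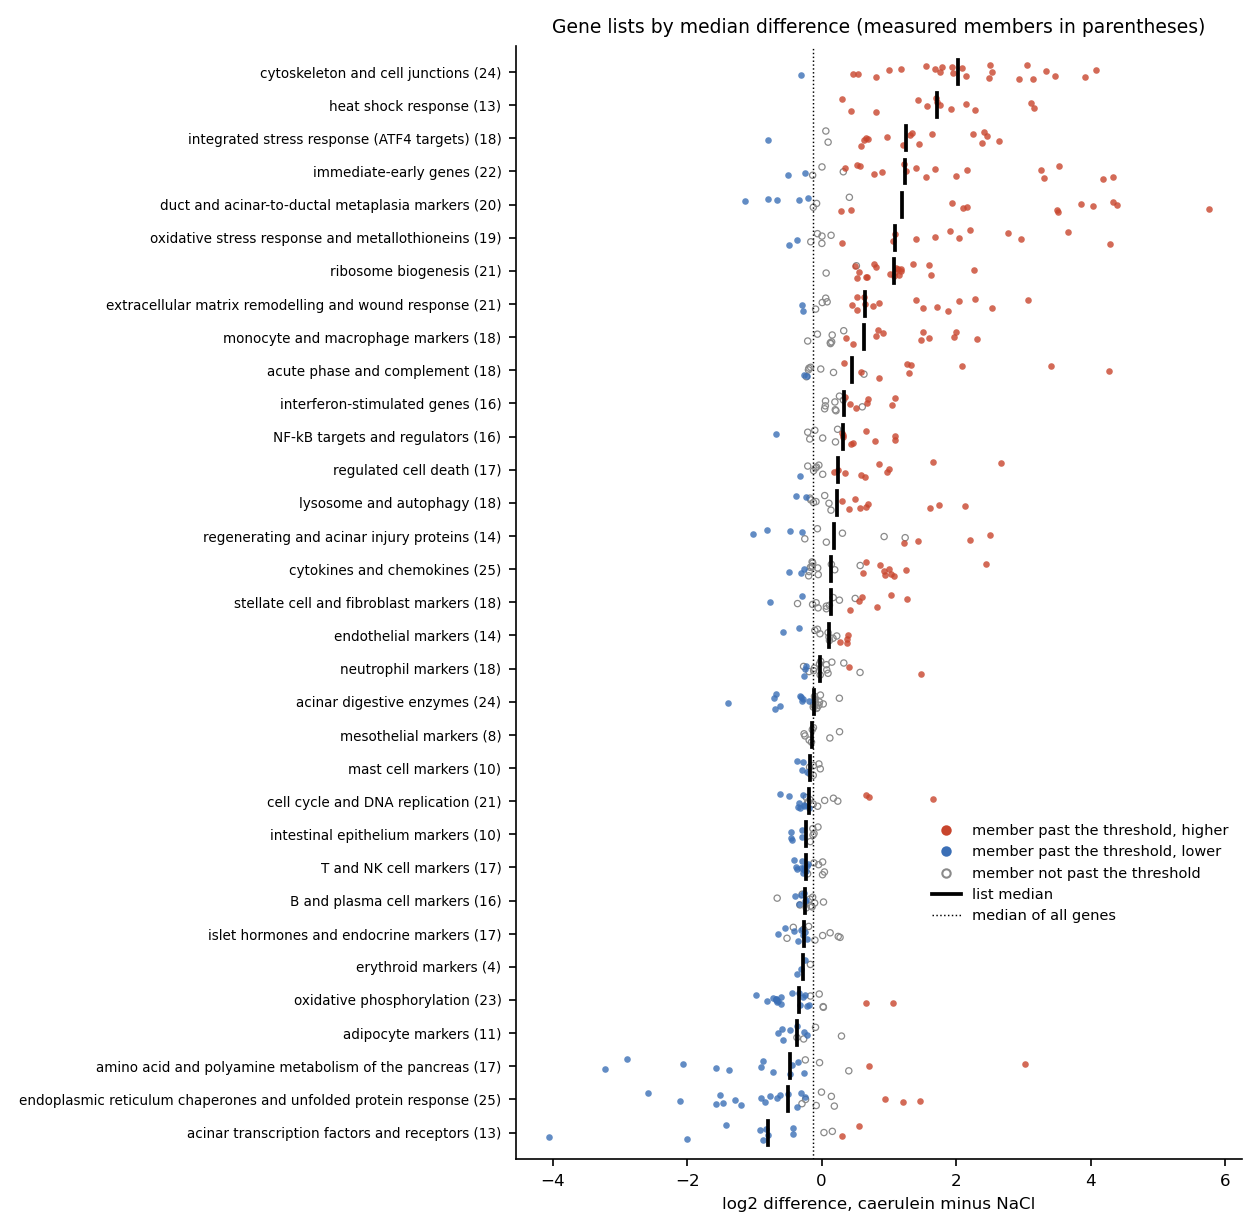
Log2 difference, caerulein minus NaCl, of each measured member of the 33 gene lists (points, filled where past the threshold) with the list median (bar) and the median of all genes (dotted line, -0.13). List medians as deposited run from -0.80 for acinar transcription factors and receptors to 2.03 for cytoskeleton and cell junctions; with an equal scaling list mean all of them move down by 0.56, and 9 change sign.

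The named genes near the threshold were less stable when arrays were left out in turn. Here the parentheses give the limma adjusted p with all arrays, and its highest value where leaving out an array ended the call. The tight-junction gene Cldn1 had a difference of -0.31 (limma adjusted p = 0.0414) and kept its call only without NaCl replicate 1 or caerulein replicate 1, with adjusted p up to 0.0915 otherwise. Epb42, with a difference of -0.30 (0.0404), kept it only without NaCl replicate 4 or caerulein replicates 2 or 4 (up to 0.0944 otherwise). Cat, which encodes catalase, had a difference of -0.48 (0.0295) and lost its call without NaCl replicates 1 or 4 or caerulein replicates 1, 2 or 3 (up to 0.0726). Fgf21, a secreted metabolic hormone, had a difference of -0.80 (0.0303) and lost it without NaCl replicates 1 or 2 or caerulein replicates 1, 3 or 6 (up to 0.0722). Mmp8, a neutrophil collagenase, was higher by 0.41 (0.0249) as deposited and -0.15 with an equal scaling list mean, and lost its call without NaCl replicates 2, 3 or 4 or caerulein replicates 4 or 6 (up to 0.0626). The plasma cell gene Mzb1, with a difference of -0.40 (0.0295), lost it without NaCl replicate 3 or caerulein replicates 1, 4 or 5 (up to 0.0653), and the perforin gene Prf1, with a difference of -0.41 (0.0287), without NaCl replicates 3, 4 or 5 (up to 0.0730). Cldn1, Epb42, Mzb1 and Prf1 were also not called after a second quantile normalisation or cyclic loess. The mesothelial gene Lrrn4 (-0.25, limma adjusted p = 0.0511) passed without NaCl replicate 5 or caerulein replicates 2 or 4 (down to 0.0282). The other 81 of 89 named genes kept their side of the threshold whichever array was left out.

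Of the 32 lists tested, 20 passed camera, 15 higher and 5 lower. Across all lists 369 of 566 memberships passed over all probe sets and 380 adjusted over the list alone; where no second count is given for a list, both counts were equal. With an estimated correlation 3 lists kept their call (immediate-early genes, ribosome biogenesis, and cytoskeleton and cell junctions), and 9 of 100 splits of the arrays, the real one included, gave 20 or more list calls. Splits that divide the NaCl arrays unevenly can hold part of the group difference, so this number is no clean measure of chance. The other splits gave a median of 13 list calls, so chance was not excluded for the number of list calls. With an equal scaling list mean, lower members outnumbered higher ones among cytokines (14 against 5), NF-kB targets (9 against 2), acute phase genes (7 against 6), interferon-stimulated genes (7 against 2), lysosome genes (10 against 3), cell death genes (9 against 5), fibroblast markers (11 against 2) and endothelial markers (11 against 0). The self-contained test fry called 30 lists, 18 higher and 12 lower.

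**Figure D3:**
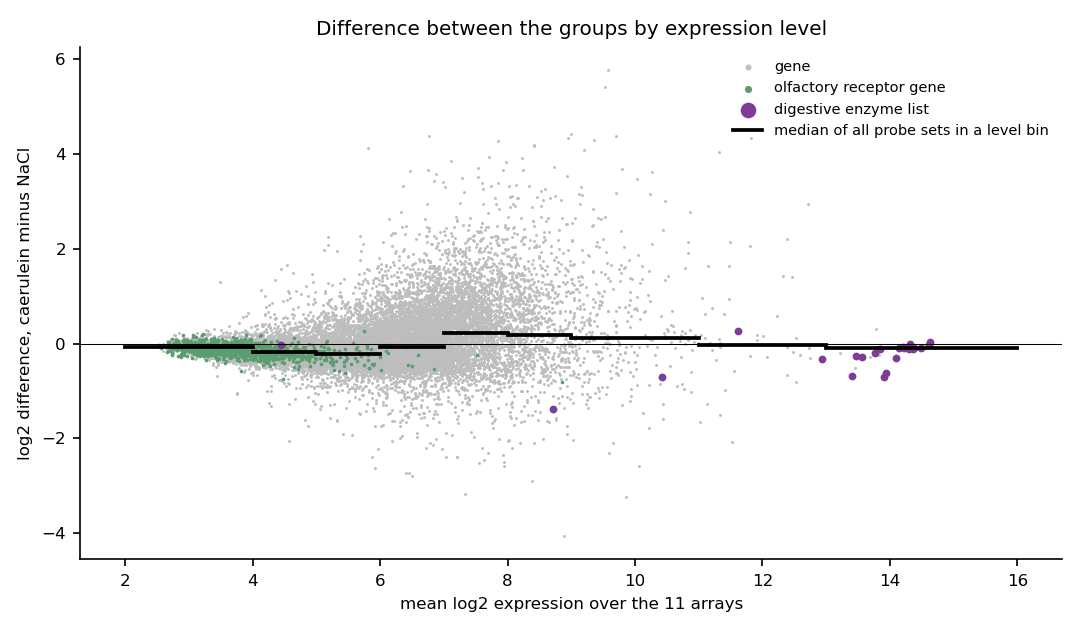
Log2 difference, caerulein minus NaCl, of 19938 genes (grey points) against their mean log2 expression over 11 arrays. Olfactory receptor genes are in green, the digestive enzyme list is in purple, and black bars give the median of all probe sets in each level bin. The bin medians are -0.21 between levels 5 and 6, 0.22 between 7 and 8 and -0.09 above 13, where 19 of 24 members of the digestive enzyme list lie.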

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

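The checks on olfactory receptor calls, on the share of acinar cells and on duct cells were chosen only after the results they measure had been seen; the other tests here were set beforehand.

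More probe sets were lower than higher in caerulein, and part of this may be a downward shift of dim signals left by the normalisation. The 1027 olfactory receptor genes, taken as silent in pancreas, had a median difference of -0.12442 (bootstrap interval -0.13 to -0.12), close to -0.12 for the dimmer 50 percent of the probe sets. A true fall of expressed genes predicted that lower calls would stay the majority without the dimmer 50 percent and after a second quantile normalisation, and they did, at 54.1% (exact binomial interval 53.2 to 55.0) and 56.3%. After cyclic loess, added later, the share was 46.4%. The cut lay between levels 5 and 6, where 3119 probe sets were lower and 663 higher, with a median of -0.21. Part of these stayed in, so leaving out the dimmer 50 percent does not separate a shift of dim signals from a true fall. Between levels 6 and 7, 2182 were lower and 1742 higher, and between 7 and 8, 947 were lower and 1750 higher. In the later check 204 olfactory receptor genes were called lower and 0 higher (limma; interval 17.5 to 22.4 percent lower), but their mean level of 3.79 lies near the floor, so they exclude nothing about expressed genes. The binomial intervals treat probe sets and genes as independent, although all share the same 11 arrays, so they overstate the precision. Both explanations stay open.

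The duct and metaplasia list rose, which a lower share of acinar cells or more duct cells could bring about. The first would raise every other cell type by about the duct list median of 1.19, but the upper bootstrap bounds of the islet, endothelial and fibroblast medians were -0.10, 0.27 and 0.50, and 0 of 17 islet markers were higher. With the duct list median taken as fixed, the values argue against a lower acinar share as the whole cause of that median. A smaller contribution is not excluded. The smallest gap between the medians was 1.05. With the duct list resampled as well, the lowest of the lower bootstrap bounds of these gaps was -0.32. Not every gap lay beyond its bootstrap spread, so this stricter check was not met and does not decide. For the 12 members that rose the gap was 3.36, which decides nothing because they were chosen for having risen. More duct cells would raise duct factors and channels alike. The 7 measured (Sox9, Cftr, Onecut1, Onecut2, Prom1, Muc1 and Car2, chosen after their values were seen) had a median of -0.20, or 3.70 below the other members (interval 1.66 to 4.51), but this decides nothing either because of that choice. More duct cells and changed expression within acinar or duct cells stay open, and the latter was not tested.

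Digestive enzymes moved little as deposited, and compression near the top of the array's range is a candidate explanation. Among 8 bright genes outside the enzyme list, with a mean level of 13 or more, the spread of differences was 0.213 times that of probe sets between 9 and 11 (interval 0.067 to 0.305). Of the 19 members of the enzyme list at 13 or more, 7 were lower with a median of -0.10. Of the 5 below 13, 3 were lower with a median of -0.33. A true lack of change in the bright enzymes was not separated from compression.

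Across 100 splits of the 11 arrays, the real one included, chance can be excluded for the counts of probe sets and genes: only 1 split, the real one, reached 15713 probe sets (highest other 10769), 2109 at 2-fold (highest other 1480) and 10890 genes (highest other 7618). The 2 other splits that kept all NaCl arrays together called 10769 and 10301 probe sets, and splits that parted them called at most 1, so these counts follow the structure of the samples. For the 20 gene lists chance was not excluded. Of the 100 splits, 9 gave as many and the highest other gave 22, which by the rule set beforehand counted for chance. The other splits called a median of 13 lists. A split with 2 NaCl arrays in its first group called 17 lists and 0 genes. Camera with the preset correlation therefore called lists where no gene passed. Splits that gave 22 had 1 or 3 NaCl arrays in their first group. They may hold part of the difference between the groups, so the splits do not decide about chance.

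In 17 of 248 groups of arrays a single array stood apart by Dixon's ratio, against 12.4 expected by chance. Caerulein replicate 1 stood apart 6 times, in Gatm (ratio 0.629), Prf1 (0.680), Bbc3 (0.684), Cldn1 (0.669), the mean of the NF-kB list (0.637) and its mean correlation with its own group (0.793; 0.984 against 0.987 for the others). NaCl replicate 3 stood apart 5 times, in Mzb1 (0.845), Lcn2 (0.746), Fgg (0.712), Thbs1 (0.715) and the mean of the cell death list (0.731). NaCl replicate 4 stood apart in Pdpn (0.760), Epb42 (0.791), Serpina3n (0.903) and the mean of the macrophage list (0.744), and NaCl replicate 1 in Hsp90aa1 (0.734) and the mean of the duct list (0.790). Without caerulein replicate 1, 5620 probe sets were higher and 9254 lower. Dixon's ratio looks for single arrays and cannot show a group that divides. On the second principal component, caerulein replicates 1 to 3 lay between 7.51 and 35.3 and replicates 4 to 6 between -19.5 and -13.9. Among genes picked after their values were seen, Nfkbia was 8.30 to 8.96 in the former and 7.63 to 7.86 in the latter. Reg3b also divided this way and Cldn4 did not. The cause was not tested.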

How the results depend on the processing

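Cyclic loess normalisation was chosen after the data had been seen. With an equal scaling list mean, 31306 probe sets passed (2338 higher, 28968 lower), 4429 with 2-fold change (627 and 3802), 18062 genes (1691 and 16371) and 1 list lower. The scaling list itself was 0.56 higher in caerulein, with 6 of its 10 genes higher and 0 lower, so this shift lowers every difference by construction; Ptf1a (-0.0098), Mmp8 (-0.150) and Pecam1 (-0.173) reversed. After a second quantile normalisation, 603 probe sets were lower at 2-fold, and the mesothelial (-0.0757) and cell cycle (-0.0681) lists reversed their test direction. Without the dimmer 50 percent, where fewer probe sets were tested, 6446 probe sets and 4492 genes were lower, and the neutrophil (-0.172) and cell cycle (-0.173) lists reversed. After cyclic loess, 5467 probe sets and 3636 genes were lower, and the mesothelial (-0.0382) and cell cycle (-0.0165) lists reversed. For these reversals the cause was not tested; none of these lists passed camera in these settings.

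At an adjusted p under 0.01, 10415 probe sets passed, with 5712 probe sets and 4125 genes lower. With treat, 926 probe sets passed (785 higher, 141 lower), because it tests against 2-fold. Camera with an estimated correlation called 3 lists, 3 higher and 0 lower, and fry, which tests no contrast with other genes, called 12 lists lower. A trended robust prior, array weights, equal 75th percentiles, the exact rank-sum test and the mean of all probe sets of a gene left the counts of probe sets, genes and lists past the threshold that they apply to within 1.5 times. Counts of members within lists moved further: with equal 75th percentiles the lower members went from 10 to 19 in the enzyme list, 6 to 12 in the B cell list, 3 to 6 among cytokines, 1 to 3 among NF-kB genes and 2 to 5 in the acute phase list.

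With 1 array left out in turn, counts ran from 14148 to 14993 probe sets (5471 to 5753 higher, 8645 to 9338 lower), 2075 to 2162 at 2-fold (1684 to 1782 and 366 to 402), 9862 to 10446 genes (3870 to 4011 and 5989 to 6497) and 19 to 22 lists (14 to 16 and 5 to 6). The same replicate numbers occur in both groups but belong to mice of different treatment, and pairs of the same number deviated with correlations of 0.057, 0.025, 0.060, -0.052 and 0.032; 2 of 5 NaCl samples matched their own number best. With the replicate block, 5452 probe sets were higher and 7909 lower, 1702 and 401 at 2-fold, with 3750 genes higher and 5477 lower, and the adipocyte list passed camera (adjusted p = 0.0329). Signal over background was not analysed here and limits what can be said of dim probe sets.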

Other observations

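Apart from the lymphocyte, mast cell and intestinal lists, the gene lists in this part were drawn up after the values had been seen. The comparison with level-matched random lists was added then too. For lists drawn up in this way, the matched ranges describe the members and are no independent support. The rules for reading the tests were set before their results. For the clock genes and the lymphocyte lists the reading was changed afterwards, as said there.

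Genes of branched-chain amino acid breakdown were lower in caerulein for 22 of 24 measured members and higher for 1 (limma), with a median of -1.39. The log2 difference was -2.58 for Aldh6a1, -2.40 for Acadsb, -2.20 for the propionyl-CoA carboxylase gene Pcca and -2.03 for Ivd. Dld was 0.49 higher as deposited, less than the 0.56 by which the scaling list rose. Because 5 members were among the 40 largest falls, the other 19 were tested alone. Their median of -1.28 lay below the range of 10000 matched random lists (-0.19 to 0.66), as a fall across the pathway predicted. All members were listed after their values had been seen, so this is no independent support. It shows only that the fall was not confined to those 5 members.

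Genes of protein translocation and secretory transport were lower for 17 of 26 members and higher for 2, with a median of -0.53 against -0.17 to 0.63 in matched lists; 25 were lower with an equal scaling list mean. The difference was -1.29 for Tmed6, -1.23 for the signal peptidase gene Spcs2 and -1.03 for Sec62, while Kdelr3 was 0.88 higher. Among MAP kinase feedback genes, receptors and receptor ligands, 12 of 21 were higher and 3 lower, with a median of 0.66 against -0.27 to 0.34 in matched lists. The counts were 7 higher and 8 lower, with a median of 0.10, with an equal scaling list mean. Egfr, the epidermal growth factor receptor gene, rose by 3.35 and Erbb3 by 2.07, the ligand gene Btc rose by 2.22 and the feedback inhibitor gene Errfi1 by 1.85. These were among the largest rises of the list. Dusp4, Dusp6, Spry4, Spred3, Etv5 and the ligand gene Tgfa did not pass, and Dusp2 (-0.32), Spry1 (-0.26) and Etv4 (-0.27) were lower.

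Clock output and repressor genes were lower for 9 of 10 members, with a median of -1.18 against -0.33 to 0.52 in matched lists. The difference was -1.57 for Ciart and -1.29 for Per3, and Nr1d1 was 1.02 higher. Of the 4 genes taken as the opposite limb, the activators Arntl and Clock and the repressors Cry1 and Nfil3, 3 were higher as deposited: Nfil3 by 3.94, Arntl by 0.74 and Clock by 0.55, the last less than the 0.56 by which the scaling list rose. Of these 4, 1 was higher and 1 lower with an equal scaling list mean. As deposited, their median of 0.64 lay inside the matched range of -0.46 to 0.79. A different clock phase in the groups could part these limbs, and without Dbp and Nfil3 their medians lay 1.62 apart. With 9 genes against 3 the exact two-sided permutation p was 0.0818, which by the rule set beforehand counted against the explanation. That rule was too strict, since a missed p with 3 genes on one side does not show that the limbs moved alike while their gap exceeded the bound of 0.5, so the explanation stays open; time of day at collection is not given in the sources used here.

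Sterol synthesis genes as a list did not fall relative to genes of similar level. As deposited 7 of 20 were higher and 6 lower, against 3 and 15 with an equal scaling list mean (median -0.50). The 19 members outside the 40 largest falls had a median as deposited of 0.12 (0.11746), inside the matched range of -0.30 to 0.24. Fewer lymphocytes, mast cells or intestinal cells could lower their 4 lists. The median of their 53 members, -0.22736, lay just under the matched range of -0.22614 to -0.12, which nominally met the rule. The distance of 0.0012 is less than the bootstrap standard error of 0.0268, and each list alone lay inside its own range (percentiles 10.6, 15.3, 36.0 and 13.1), so this cannot be told apart from no change relative to genes of similar level.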
